A study of Mus musculus with 16 samples.

How the data were processed

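The measurements came from RNA immunoprecipitation followed by array hybridisation (RIP-chip) in HL-1 cells, a line of mouse atrial cardiomyocytes. Per the labels, cells were transfected with a scrambled siRNA or an siRNA against Airn, each at 10 nM, and RNA was precipitated with an antibody against the RNA-binding protein Igf2bp2 or with control IgG. Total RNA was extracted, and biotinylated cRNA was hybridised to Affymetrix arrays, per the labels' protocols. The 4 groups (antibody by siRNA) held 4 biological replicates each, 16 arrays in all, registered in 2 rounds.

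The values used here were the authors' own comparisons. Per the file headers, the authors' deposited table gave 35556 rows, each with a transcript cluster identifier. For each row it gave the log2 difference between anti-Igf2bp2 and IgG precipitates, its p-value and its adjusted p-value. These were given once for the scrambled and once for the Airn siRNA. That the deposited differences are on the log2 scale follows the header's wording and was not tested on intensities. The software, normalization, filters and statistical model behind these values are not given in the sources used here. The deposited adjusted p-values equalled Benjamini-Hochberg values recomputed from the deposited p-values within 0.00023 wherever p was at least 0.001. Values of single arrays were not used here, so signal over background and the spread between replicates could not be examined, and the number of arrays limits the precision.

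Of the rows, 22406 carried a single gene symbol, 2824 carried several, 10302 carried none, and 24 carried a symbol that had been turned into a date. The plan left out control rows, but no such filter was applied, so all rows entered the counts, medians and correlations over all rows. They include 6615 rows without a symbol whose identifiers precede the first named row. Whether these are array controls was not examined. Among 20170 distinct single symbols, 17433 were current symbols in the RefSeq annotation of the mouse assembly GRCm38.p6 and 2024 were a synonym of 1 current gene. Gene names are those of the table, with the current symbol added where it differs. No coordinates are printed because no genome build was named.

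The planned fit of a linear model to the arrays could not be made on a table of comparisons. In its place, each row's standard error was recovered from the deposited difference and p. A single value of 16.13 degrees of freedom gave the same standard error in both comparisons, with a median disagreement of 0.065% over 29524 rows. This is what 1 moderated model with a shared spread per row gives. Printed p-values below 5e-05 have few digits and were taken back from the adjusted p and its rank. The standard error could not be recovered for 2 rows. Since the comparisons rest on different arrays, their errors were taken as independent: the change of enrichment is the Airn-siRNA value minus the scrambled-siRNA value, and the average is their mean. Both were tested against a t distribution with the recovered degrees of freedom and adjusted by the Benjamini-Hochberg method over all rows. A row counted as called at an adjusted p under 0.05, with no fold minimum.

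The recovery was tested on simulated arrays analysed with limma 3.58.1 in R 4.3.3 and rounded like the deposited table. For the change of enrichment over 35554 simulated rows, the recovered values gave the same 60 calls as limma itself. They included 54 of 100 rows changed 4-fold and 2 of 100 rows changed 2-fold, with 4 calls among 35354 unchanged rows. Where simulated replicate effects were left out of the fit, 17 of 100 rows changed 4-fold and 0 of 100 changed 2-fold were called. With 100 rows changed at each size, the test of the change therefore had little power for 2-fold changes of single genes. Its power for 4-fold changes depends on whether replicate effects were fitted, which is not given in the sources used here. Power with more changed rows was not simulated and can differ, because the adjustment depends on how many rows change.

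The 34 gene lists and the rule for named genes were fixed before the data were examined. A gene with several rows (1304 genes) was represented by the row with the smallest recovered standard error, because the table gives no mean levels for the planned choice. Lists with at least 5 measured members were tested with limma's cameraPR on the recovered statistics, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. A correlation could not be estimated without array values, so the tests were repeated with an assumed correlation of 0.1. For each comparison, the 10 called genes with the largest differences in each direction were named, or, without calls, the 5 with the smallest p. The 4 members of each list with the largest differences, and Airn, Igf2r, Igf2bp1, Igf2bp2, Igf2bp3, Igf2, H19 and Actb, were named as well. Predicted and clone-named genes, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors were left out of the first part of that rule. The condition that all replicate pairs share a sign could not be applied. A common line was drawn through both comparisons as the principal axis over genes, and deviations from it were tested in the same way; this step was added after the data were seen.

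The alternatives tried were 1 row per gene, a 1.5-fold minimum, rows with a single symbol, centring on the median, other thresholds, correlated errors, rescaled errors and other settings of the list test. Direct comparisons of the siRNAs within the Igf2bp2 or the IgG precipitates need array values and were not analysed here. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.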

Results

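RNA bound by Igf2bp2 was compared with RNA recovered by control IgG in HL-1 mouse atrial cardiomyocytes, after transfection with a scrambled siRNA or an siRNA against Airn. Airn is a long non-coding RNA transcribed antisense to Igf2r, and Igf2bp2 is an RNA-binding protein that acts on the stability, transport and translation of mRNA. The 16 arrays formed 4 groups of 4 biological replicates. Each value below is a log2 difference between anti-Igf2bp2 and IgG precipitates, so that a positive value means a higher value of an RNA in the Igf2bp2 precipitate. Whether values are relative to the array's other RNAs depends on the normalization, which is not given in the sources used here. Errors are standard errors (SE) recovered from the deposited difference and p, and values of single arrays were not used here.

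The targeted and related transcripts were examined first. Igf2bp2 mRNA itself was higher in the Igf2bp2 precipitates with both siRNAs in the authors' deposited table, by 0.74 ± 0.20 with the scrambled siRNA (adjusted p = 0.0175) and by 1.00 ± 0.20 with the Airn siRNA (adjusted p = 0.0413). The difference between these values was 0.26 ± 0.29 (95% interval -0.35 to 0.87). For Airn, the authors' deposited table gave 0.48 ± 0.21 and 0.38 ± 0.21 in the more precise of its rows, with adjusted p of 0.0785 and 0.197. Airn was thus not called as precipitated by Igf2bp2 in either condition. Averaged over both siRNAs, this Airn row stood at 0.43 ± 0.15 (adjusted p = 0.023), a call made from the combined value alone. The average called 58.2% of all rows. The less precise Airn row stood at 0.50 and 0.44, each ± 0.29, with adjusted p of 0.170 and 0.272 in the authors' deposited table. These differences compare antibodies within one siRNA and do not measure how far Airn was silenced. Igf2r, the gene that Airn overlaps, stood at -0.09 and -0.10 in the authors' deposited table and was not called. The oncofetal paralogue Igf2bp3 was lower with the scrambled siRNA in the authors' deposited table (-0.85 ± 0.29, adjusted p = 0.0355) and not called with the Airn siRNA (-0.41, adjusted p = 0.303). The difference between these Igf2bp3 values was 0.44 ± 0.41 and was not called (adjusted p = 0.998 in the recovered test). Igf2bp1 was not called in the authors' deposited table (0.33 and 0.20), and a further Igf2bp1 row had the opposite sign (-0.31 and -0.19). H19, an imprinted non-coding RNA, stood at 0.76 (adjusted p = 0.0376) and 0.90 (adjusted p = 0.0735) in the authors' deposited table, and a row shared by H19 and Mir675 stood at 0.20 and 0.10 and was not called. Igf2 stood at -0.47 and -0.49 in the authors' deposited table and was not called. Actb, which encodes beta-actin, was higher with the scrambled siRNA (0.79 ± 0.19, adjusted p = 0.0128) in the authors' deposited table and stood at 0.56 with the Airn siRNA (adjusted p = 0.0901). In the average over both siRNAs, the more precise rows of Igf2bp2, H19 and Actb were also called higher and those of Igf2 and Igf2bp3 lower. Igf2bp1 and Igf2r were not called in it. No transcript of this paragraph was called in the difference between the siRNAs.

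With the scrambled siRNA, many transcripts of metabolic, translation and secretory genes were higher in the Igf2bp2 precipitates. Leukocyte, neuronal and sensory receptor genes had more members lower than higher. The authors' deposited table called 13248 of 35556 rows at an adjusted p under 0.05, 7269 higher and 5979 lower. The highest named transcripts in the authors' deposited table were Utp18, a component of the small-subunit processome (1.94 ± 0.43, 3.85-fold, adjusted p = 0.00985), and Exosc2, a subunit of the RNA exosome (1.83 ± 0.31, 3.55-fold, adjusted p = 0.00529). Arpc5 of the actin-nucleating Arp2/3 complex (1.73), Etohi1 (now Zfp971, 1.72), Naa38 (1.70), Tmem50b (1.66), Wdr45l (now Wdr45b, 1.65), Gtf3c6 of a transcription factor for RNA polymerase III (1.65), cardiac troponin C Tnnc1 (1.64) and the purine enzyme Adss (1.63) followed in the authors' deposited table. The lowest named transcript was the mitochondrial ND6 (-2.59 ± 0.34, 6.04-fold, adjusted p = 0.00165) in the authors' deposited table, followed by the vault RNA Vaultrc5 (-2.10 ± 0.39, 4.29-fold, adjusted p = 0.00668). Lower values in the authors' deposited table also included Serpina1c (-1.81), which encodes a liver protease inhibitor, the Y RNA Rny1 (-1.76), the liver cytochrome Cyp2c38 (-1.74), Resp18 (-1.73), Sp5 (-1.64), Tceal6 (-1.62) and the immunoglobulin segment Igk-V21-2 (now Igkv3-2, -1.60). Moxd2 stood next, at -1.597 in the authors' deposited table.

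In the lists of nuclear-encoded oxidative phosphorylation, ribosomal proteins, translation factors, fatty-acid oxidation and glycolysis, every call was on the higher side, though not every member was called. Of 73 nuclear-encoded oxidative phosphorylation genes, 40 were called higher and none lower in the authors' deposited table (49 higher adjusted over the list alone), with a median of 0.67. Examples in the authors' deposited table were Ndufs4 (1.38) and Ndufa9 (1.19). Among 38 genes of the secretory pathway and translocon, 29 were called higher and none lower in the authors' deposited table (35 higher and 1 lower adjusted over the list alone), with a median of 0.81, including the signal recognition particle receptor Srpr (1.28) and the signal peptidase subunit Sec11c (1.21). Cytosolic ribosomal proteins had 37 of 61 members higher in the authors' deposited table (39 adjusted over the list alone), led by Rpl23a (1.29), and mitochondrial ribosomal proteins had 32 of 57 (37 adjusted over the list alone), led by Mrpl23 (1.43). Translation factors had 28 of 37 members higher in the authors' deposited table (34 adjusted over the list alone), among them Eef1a1 (1.24) and Eif4e (1.08). RNA-binding proteins and splicing factors had 34 of 42 members higher and 1 lower in the authors' deposited table (37 and 1 adjusted over the list alone), with Hnrnpa3 at 1.30 and the lower Lin28b at -0.81. The N6-methyladenosine machinery, whose mark is read by Igf2bp proteins, had 11 of 13 members higher in the authors' deposited table (12 higher and 1 lower adjusted over the list alone), with Wtap at 1.05 and the demethylase Fto at 0.95. In the proteasome list 21 of 30 members were higher in the authors' deposited table (24 adjusted over the list alone), with Psmd6 at 1.39, and in the list of fatty-acid oxidation and the tricarboxylic acid cycle 25 of 31 (30 adjusted over the list alone), with Dld at 1.27. The authors' deposited table had 15 of 20 glycolysis genes higher (17 adjusted over the list alone), 25 of 36 actin cytoskeleton genes (32 adjusted over the list alone) and 21 of 36 cell cycle genes (33 adjusted over the list alone). Cholesterol synthesis and lipoprotein receptors had 18 of 29 members higher and 1 lower in the authors' deposited table (21 and 2 adjusted over the list alone), with Idi1 at 1.31. All of these lists passed the cameraPR test against the other genes, with adjusted p from 1.55e-08 for oxidative phosphorylation to 0.000842 for the N6-methyladenosine list at the preset correlation. With an assumed correlation of 0.1, 13 lists of 34 passed in place of 20. The genes compared against were not limited to expressed ones, and 96.6% of sensory receptor rows, for instance, lay below 0. These tests therefore cannot tell selective binding by Igf2bp2 apart from expression of the listed genes in these cells.

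In the cardiac lists, calls were mostly on the higher side, but most members were not called. Of 28 sarcomere genes, 12 were called higher and none lower in the authors' deposited table (15 adjusted over the list alone), with Tnnc1, Myoz2 (1.00), Myom1 (0.87) and cardiac actin Actc1 (0.84) in front. The list passed cameraPR (adjusted p = 0.00065), but not with an assumed correlation of 0.1 (adjusted p = 0.0687). Among 35 ion channel and calcium-handling genes, the authors' deposited table called 13 higher and 2 lower (the same counts adjusted over the list alone), with connexin 43 Gja1 at 1.19 and phospholamban Pln at 0.91, and the acetylcholine-gated potassium channel Kcnj3 at -0.81. Of 17 cardiac transcription factors and atrial peptides, 6 were higher and 1 lower in the authors' deposited table (the same adjusted over the list alone), with Tbx5 at 0.69 and Isl1 at -1.04. The 31 RNAs listed as reported targets of Igf2bp proteins had 14 members higher and 2 lower in the authors' deposited table (15 and 3 adjusted over the list alone), with Btrc at 1.07, Ccnd2 at 1.05 and Tgfbr1 at 1.00, and this list did not pass cameraPR (adjusted p = 0.0524).

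Among markers of leukocytes, neurons and endothelium, nearly all calls were on the lower side, while those of smooth muscle and fibroblasts went both ways. Of 22 leukocyte markers, 9 were called lower and 1 higher in the authors' deposited table (12 and 1 adjusted over the list alone), with S100a8 at -1.28 and Lyz2 at -1.17. Neuronal markers had 7 of 14 members lower in the authors' deposited table (7 adjusted over the list alone), with Elavl4 at -1.10, and endothelial markers had 5 of 20 (1 adjusted over the list alone), with Emcn at -0.72. These lists passed cameraPR, with adjusted p of 0.000613, 0.00262 and 0.0186. With an assumed correlation of 0.1 adjusted p was 0.0523, 0.0546 and 0.175. Smooth muscle markers had 5 of 15 higher and 3 lower in the authors' deposited table (8 and 3 adjusted over the list alone), with Cnn1 at 1.06, and fibroblast markers 4 of 20 higher and 3 lower (7 and 6 adjusted over the list alone), with Dpep1 at 1.06 and Dpt at -1.04. Sensory receptor genes had 474 of 1271 rows lower and 2 higher in the authors' deposited table, with a median of -0.66. Imprinted genes were divided, with 8 of 35 members higher and 8 lower in the authors' deposited table (10 and 8 adjusted over the list alone), such as Ube3a (1.00) against Peg3 (-1.07) and Meg3 (-0.92). The median over all rows was -0.10, and with the comparison centred on it 68.8% of calls were higher, against 54.9% without centring.

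**Figure D1:**
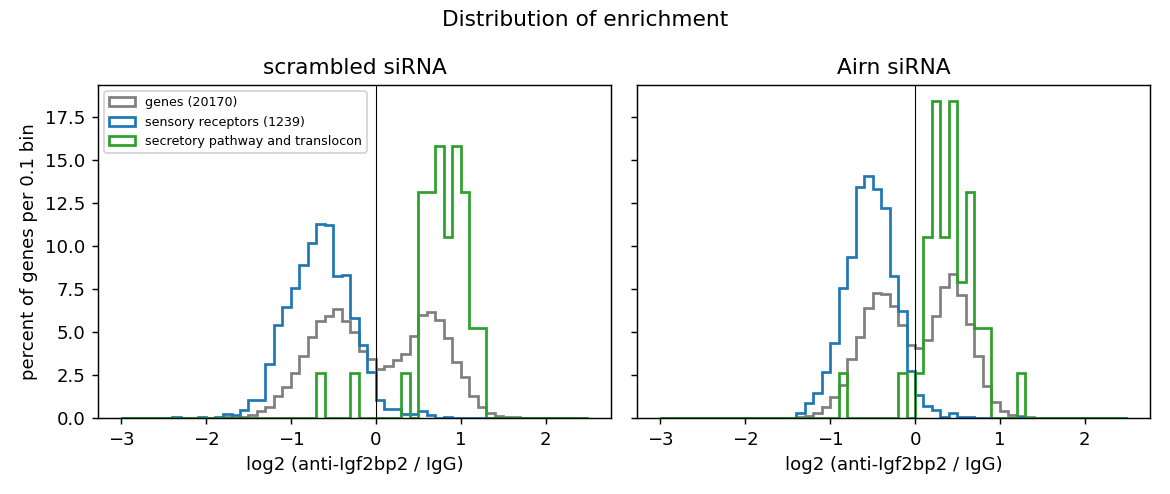
Share of genes (percent per bin of 0.1) by log2 difference between anti-Igf2bp2 and IgG precipitates, with the scrambled siRNA on the left and the Airn siRNA on the right. Lines show genes with a single symbol (20170), sensory receptors and the secretory pathway list, whose medians with the scrambled siRNA were -0.66 for receptor rows and 0.81 for the secretory list.

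With the Airn siRNA, fewer transcripts were called, and the lowest named values were those of Rny1, Vaultrc5 and ND6. The authors' deposited table called 375 rows, 224 higher and 151 lower, while 11698 rows had an unadjusted p under 0.05. Among called transcripts, the highest named values in the authors' deposited table were those of S100a10 (1.37 ± 0.30, 2.58-fold, adjusted p = 0.0474), Bcl2l13 (1.37, adjusted p = 0.0448) and the peroxisomal Pex11a (1.34, adjusted p = 0.0383). Commd6 (1.30), the vesicle SNARE Vamp3 (1.29), Cbr4 (1.29), the splicing factor Luc7l (1.28), Thoc3 of the mRNA export complex THO (1.28), Prkx (1.28) and Tsr2 (1.22) followed in the authors' deposited table. On the lower side, the authors' deposited table listed Rny1 (-2.99 ± 0.62, 7.97-fold, adjusted p = 0.0422), Vaultrc5 (-2.67 ± 0.39, 6.36-fold, adjusted p = 0.00949), ND6 (-2.60 ± 0.34, 6.05-fold, adjusted p = 0.00352), the ribonuclease P RNA-like Rprl1 (-1.70) and the U2 small nuclear RNA Rnu2 (-1.61). Lonrf2 (-1.13), Prpmp5 (-1.0), Hoxb6 (-0.97), Mab21l2 (-0.93) and the histone Hist1h4c (now H4c3, -0.92) were also lower in the authors' deposited table.

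Few members of the gene lists were called with this siRNA, although the medians kept their sign in the larger lists. The authors' deposited table called none of the 73 oxidative phosphorylation genes (median 0.31) and none of the 38 secretory genes (median 0.41), of which 0 and 1 passed adjusted over the list alone. Called members in the authors' deposited table included atrial myosin light chain Myl4 (0.78) among the sarcomere genes, the atrial natriuretic peptide precursor Nppa (1.03), the splicing factor Srsf4 (0.77), the transcription factor Irf1 (1.02) and, among 73 zinc-finger proteins of the Kruppel-associated box class, Zfp426 (1.14), Zfp583 (0.98) and Zfp322a (0.92). The adjustment over the list alone was made here from the authors' deposited p-values. With it, 8 of 13 N6-methyladenosine genes, 17 of 31 interferon-stimulated genes and 14 of 73 zinc-finger genes passed as higher. So did 9 of 42 RNA-binding proteins and 7 sarcomere genes. With the same adjustment, 6 of 20 histones, 3 of 22 leukocyte markers, 3 of 42 insulin and growth-factor genes and 1 N6-methyladenosine gene passed as lower. A few members of other lists also passed in either direction. In cameraPR, 24 of 34 lists passed at the preset correlation and 0 with an assumed correlation of 0.1. The number of calls depended on the rows tested: among rows with a single symbol adjusted among themselves, 36 passed, and with the comparison centred on its median 1183 passed, of which 80.1% were higher against 59.7% without centring.

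Enrichment was similar in its pattern with the 2 siRNAs and smaller in size with the Airn siRNA. Across all rows, the differences in the authors' deposited table correlated with Pearson's r = 0.80 and Spearman's rho = 0.817, and over 1 row per gene with r = 0.867; genes are not independent replicates. The comparisons share no arrays. Of the rows called with the scrambled siRNA, 98.1% had the same sign with the Airn siRNA in the authors' deposited table, against 87.8% of all rows. In both comparisons 295 rows were called, all with the same sign, against 71.2 for independent lists of these sizes. Both comparisons share 1 spread per row, so rows with small errors tend to be called together, and 71.2 is only a rough reference. The SD over rows was 0.721 with the scrambled siRNA and 0.571 with the Airn siRNA in the authors' deposited table. In the average over both siRNAs, 20687 of 35554 rows were called, 10373 higher and 10314 lower. This count takes the errors of both comparisons as independent. With an assumed correlation of 0.3 between them 16395 rows passed, and with -0.3 24411 passed. Among called genes open to naming, the highest averages were those of Cyb5 (now Cyb5a, 1.47 ± 0.28), Gtf3c6 (1.39 ± 0.22), Naa38 (1.33), Vamp3 (1.33), Rasgrp3 (1.32), Utp18 (1.32), Commd6 (1.31), Arpc5 (1.30), Dram2 (1.30) and profilin 2, Pfn2 (1.28 ± 0.13, adjusted p = 5.8e-05). The lowest averages of such genes were those of ND6 (-2.60 ± 0.24), Vaultrc5 (-2.39), Rny1 (-2.38), the U12 small nuclear RNA Rnu12 (-1.48), Rprl1 (-1.39), Adh6-ps1 (-1.35), Serpinb3a (-1.33), Gpr82 (-1.31), Ccr8 (-1.30) and Resp18 (-1.30).

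**Figure D2:**
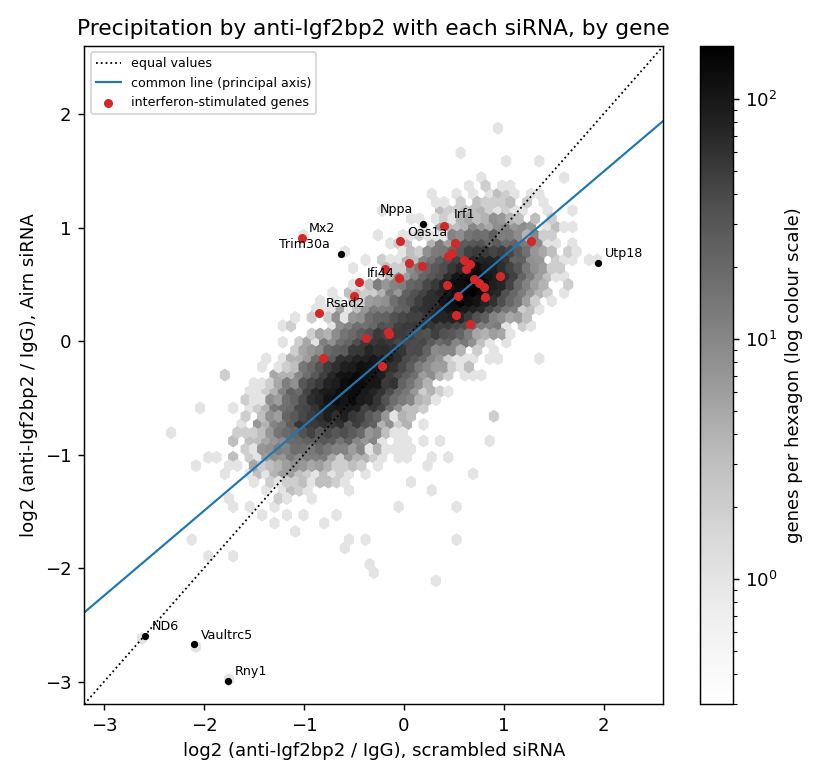
Log2 difference between anti-Igf2bp2 and IgG precipitates per gene, with the scrambled siRNA on the horizontal and the Airn siRNA on the vertical axis, shaded by the number of genes. Red points are the interferon-stimulated genes, black points other labelled genes, the dotted line marks equal values and the blue line is the principal axis, with a slope of 0.747.

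**Figure D3:**
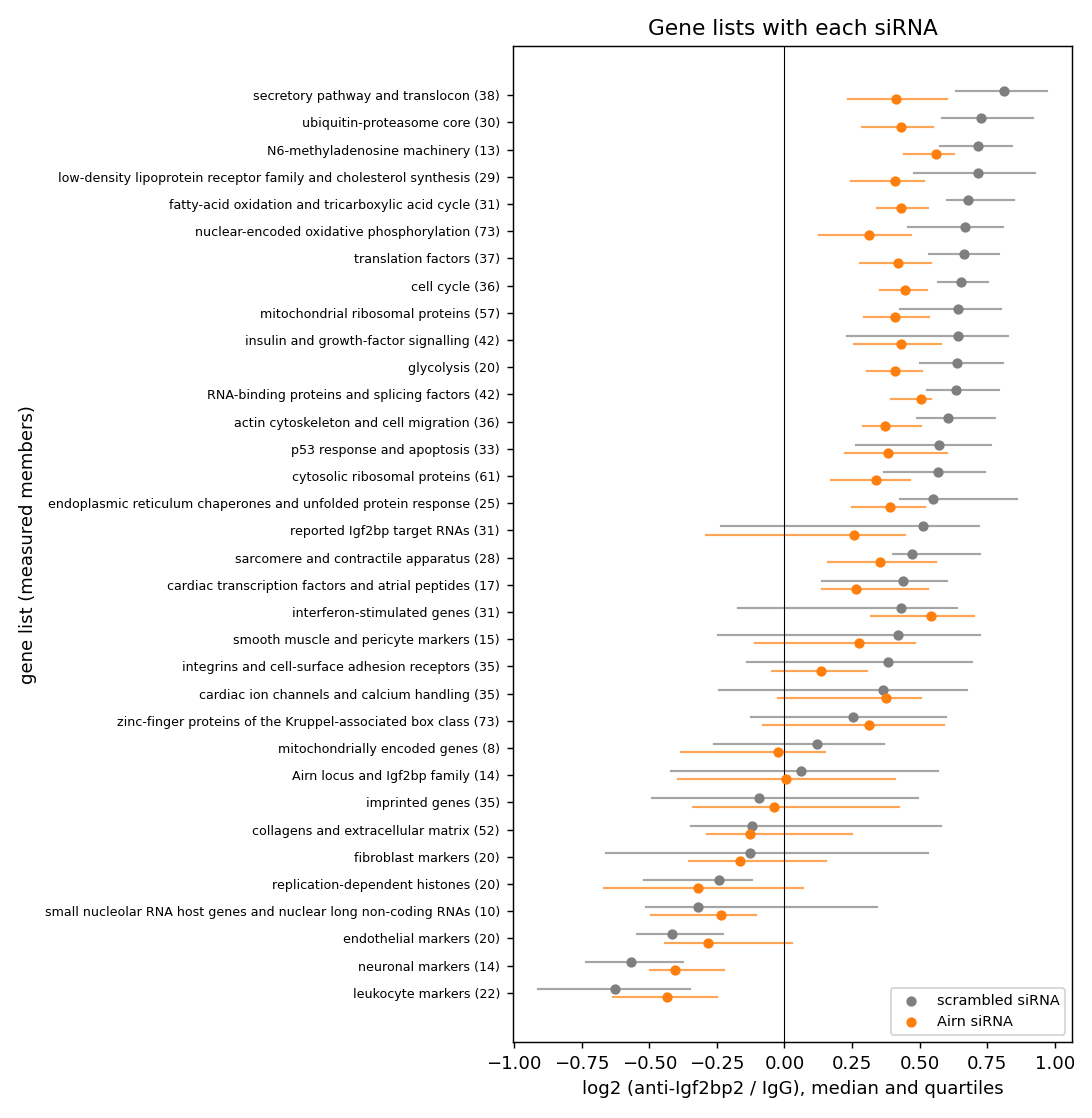
Median (points) and quartiles (bars) of the log2 difference between anti-Igf2bp2 and IgG precipitates over the measured members of each gene list, with the scrambled siRNA in grey and the Airn siRNA in orange. The secretory pathway list moved from 0.81 to 0.41, and the interferon-stimulated genes from 0.43 to 0.54.

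The change of enrichment asked which RNAs differed in the Igf2bp2 precipitates, relative to IgG, between the Airn and the scrambled siRNA. No single row passed an adjusted p of 0.05 in the recovered test (0 of 35554), and 1222 rows had an unadjusted p under 0.05, where 1778 were expected by chance. The test takes the errors of both comparisons as independent, and with an assumed correlation of 0.3 between them 2 rows passed. The largest evidence for single genes came from the antiviral GTPase gene Mx2, which stood at -1.02 with the scrambled and 0.91 with the Airn siRNA in the authors' deposited table, a difference of 1.93 ± 0.31 (p = 1.01e-05, adjusted p = 0.179). Trim30a (1.40 ± 0.26, adjusted p = 0.588), Gbp3 (0.98), Fgf6 (1.02) and Ttll11 (1.19) had the next smallest p among positive differences. Cyp39a1 (-1.03), Snhg1 (-1.50), Cdc42ep2 (-0.80), Rg9mtd1 (now Trmt10c, -0.87) and Tmem222 (-1.01) had the smallest p among negative differences of the genes open to naming, which leave out clone-named genes, each with an adjusted p of 0.998. Nppa differed by 0.84 ± 0.32 (adjusted p = 0.998) and was not called.

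At the level of gene lists, 16 of 34 passed cameraPR for the difference at the preset correlation. Oxidative phosphorylation genes fell relative to other genes, with a median difference of -0.32 and 5 of 73 members above 0 (adjusted p = 4.1e-10), as did the secretory pathway list (-0.39, adjusted p = 6.74e-07) and cytosolic ribosomal proteins (-0.24, adjusted p = 6.74e-07). Lists high with the scrambled siRNA fall with the overall scale, and the median deviations of these lists from the common line through both comparisons were smaller: -0.159, -0.175 and -0.11 (adjusted p = 3.16e-05, 0.00753 and 0.0119). With an assumed correlation of 0.1 none of these deviations passed. Interferon-stimulated genes rose relative to other genes, with a median difference of 0.24 and 21 of 31 members above 0 (adjusted p = 0.000104), and 2 members, but none in the other direction, passed adjusted over the list alone. With an assumed correlation of 0.1, adjusted p was 0.0566 for oxidative phosphorylation and the secretory pathway and 0.0838 for ribosomal proteins and interferon-stimulated genes, and 0 lists passed. Among the interferon-stimulated genes, Rsad2 went from -0.85 to 0.25, Ifi44 from -0.45 to 0.52 and Oas1a from -0.03 to 0.88 in the authors' deposited table, while Ifit2 stood at 1.28 and 0.88.

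**Figure D4:**
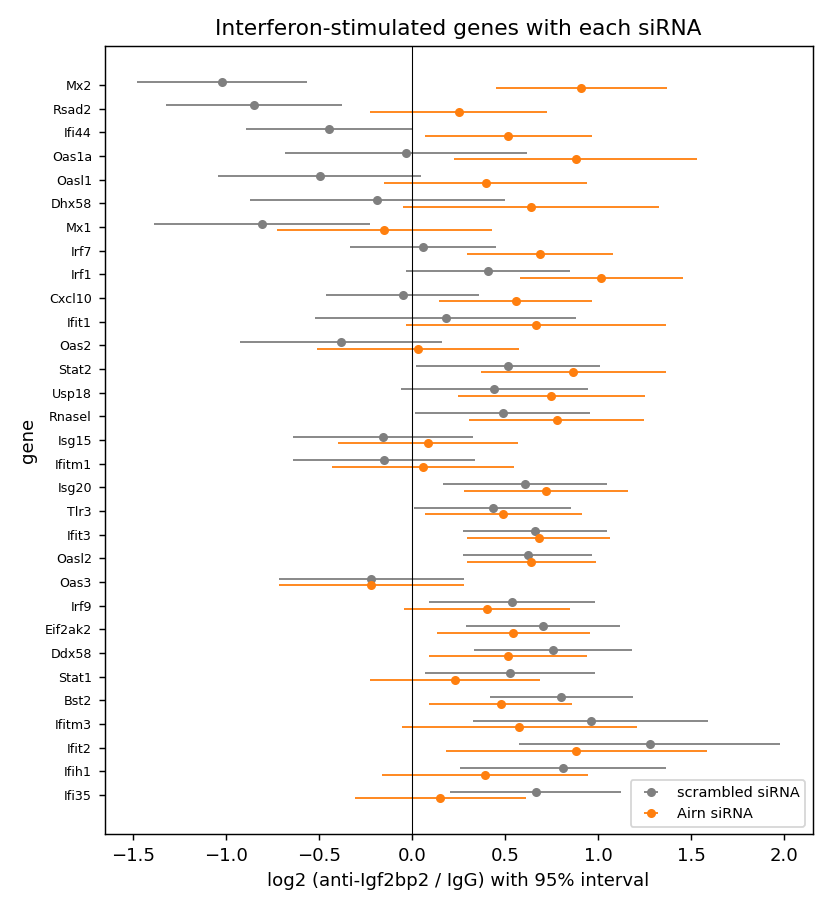
Log2 difference between anti-Igf2bp2 and IgG precipitates of 31 interferon-stimulated genes, with the scrambled siRNA in grey and the Airn siRNA in orange; bars are 95% intervals from the recovered standard errors. Mx2 shows the largest difference, from -1.02 to 0.91.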

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

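The common line and the tests of deviations from it, the larger assumed correlations, and the tests on sensory receptors and sarcomere genes were chosen after the data were seen; the list tests of the difference were planned. The bounds for the deviations were written before those values were computed. The 16 lists below are reported because their differences between the siRNAs stood apart from those of the other genes (cameraPR, preset correlation 0.01). That test takes genes as its units and does not measure the spread between replicates.

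Median differences, Airn siRNA minus scrambled siRNA, were -0.316 for oxidative phosphorylation, -0.385 for the secretory pathway and translocon, -0.243 for cytosolic ribosomal proteins, -0.278 for translation factors, -0.264 for the proteasome, -0.30 for fatty-acid oxidation and the tricarboxylic acid cycle, -0.256 for the actin cytoskeleton, -0.257 for cholesterol synthesis and lipoprotein receptors and -0.261 for the cell cycle. They were -0.217 for mitochondrial ribosomal proteins, -0.211 for RNA-binding proteins, -0.18 for insulin and growth-factor signalling, -0.208 for glycolysis, -0.223 for reported Igf2bp targets and -0.218 for integrins and adhesion receptors. The interferon-stimulated genes alone among these lists had a positive median, 0.238. Adjusted p ran from 4.1e-10 to 0.0422, and 0 lists passed with an assumed correlation of 0.1. The lists with negative medians were high with the scrambled siRNA, so the smaller overall scale lowers them too. Median deviations from the common line ranged from -0.014 for glycolysis and -0.027 for RNA-binding proteins to -0.131 for integrins, -0.159 for oxidative phosphorylation and -0.175 for the secretory pathway, and 4 lists passed for the deviation, against 1 with an assumed correlation of 0.05 or of 0.1.

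The first pattern is the gap between 13248 calls with the scrambled siRNA and 375 with the Airn siRNA. The adjustment widens it: unadjusted p was under 0.05 in 18439 and 11698 rows, and 6330 rows with the Airn siRNA met the unadjusted limit of the scrambled-siRNA calls. When the scrambled-siRNA differences were multiplied by the ratio of the SDs, 0.792, and tested with the same standard errors, 43 calls were left, fewer than the 375 observed. The multiplication shrank the error within the differences along with the signal, while the standard errors stayed the same, which lowers the count by itself. The test therefore cannot decide whether a smaller overall scale accounts for the gap. The ratio was also taken from the same comparisons, so it does not show what made the differences smaller, and losses at many genes would lower it too. A loss at single genes beyond that scale was tested by the variance of the standardised deviations from the common line, which was 0.648 times that of a t value. By the bound written before the test, at most 1.0, this value would count against such a loss; the bound was set aside after the value was seen, because errors of the right size give about 1 without any loss and 0.648 shows recovered errors larger than the scatter, so the question is left undecided. Whether the smaller scale comes from Airn silencing or from a different yield or background of these precipitates cannot be told apart without array values.

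The second pattern is the low value of genes outside the cardiac repertoire with the scrambled siRNA. Sensory receptor rows were below 0 in 96.6% of cases, and the sarcomere list had a median of 0.472 with a standard error of 0.08 over its members. Neither value decides between explanations: the receptors restate the pattern and make up 474 of 5979 lower calls, and a constant shift of every row leaves room for an enriched list above 0. Background signal of unexpressed genes and a constant shift both stay open, because no level of expression could be read from the table, and no biological explanation was tested.

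The third pattern is that interferon-stimulated genes moved against the overall scale. A smaller scale moves values toward 0 and would lower this list's median of 0.432 with the scrambled siRNA. The median was 0.543 with the Airn siRNA, so the smaller scale by itself does not give a rise of this median. The list's median deviation from the common line was 0.266 (cameraPR adjusted p = 2.27e-09, and 0.00666 with an assumed correlation of 0.1). The pattern was seen in the difference, which enters the deviation, so this test is not separate support for it. That test takes genes as its units, so a joint shift carried by only some replicates could not be examined without array values. A candidate explanation is that cells given the Airn siRNA held more interferon-stimulated transcripts, which were precipitated like other mRNA. Of 12 members below 0 with the scrambled siRNA, 10 were above 0 with the Airn siRNA, which restates the rise of the list and decides nothing between more transcripts and changed binding. Such a rise could follow from the siRNA duplex itself or from Airn depletion, and without a direct comparison of the siRNAs neither these nor a changed binding by Igf2bp2 can be told apart.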

How the results depend on the processing

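Settings other than 1 row per gene and the 1.5-fold minimum were chosen after the data were seen. No paired analysis was possible because the deposited table holds no value per array. For the same reason, these alternatives were not run although they had been planned: array scaling, the filter on dim rows, the registration round or the replicate number in the fit, the fit restricted to the compared groups, other variance models, array weights, leaving out arrays or rounds, list tests with an estimated correlation, and fry. The score of the enriched set per array, the direct siRNA comparisons and other splits of the samples could not be computed either, so regrouped samples could not be compared with the real groups.

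Of 56 values under alternatives, 36 stayed within 1.5 times the reported count or within 0.05 of the reported correlation, and 20 did not; beyond thresholds and the rows tested, the cause was not tested. With the scrambled siRNA, 13248 calls became 1305 at an adjusted p under 0.01. With the Airn siRNA, 375 calls became 66 with 1 row per gene, 36 among rows with a single symbol, 1183 after centring on the median, 5706 at an adjusted p under 0.10 and 16 under 0.01. In the average, 20687 calls became 13666 with 1 row per gene, 12868 with the 1.5-fold minimum and 10274 at an adjusted p under 0.01. The change of enrichment had 0 calls in every setting tried but one: with an assumed correlation of 0.3 between the errors of both comparisons, 2 rows passed, both higher. The correlation of 0.80 became 0.867 with 1 row per gene, 0.861 among rows with a single symbol and 0.704 among rows without a symbol. With an assumed correlation of 0.1 between genes, lists called went from 20 to 13 with the scrambled siRNA, from 24 to 0 with the Airn siRNA, from 25 to 12 in the average, from 16 to 0 for the difference and from 4 to 1 for the deviation from the common line. With 0.05 they were 10 for the difference and 1 for the deviation. Centring subtracts the median, which was -0.10 with the scrambled siRNA, and so raises every value. This turns the sign of the imprinted list's median of -0.09.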

Other observations

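Several groups of small structured RNAs had lower medians with the Airn than with the scrambled siRNA, but the fall was not equally clear in all of them. The groups in this paragraph were formed after their values were seen, so no test of them is given. Over 23 H/ACA small nucleolar RNAs, which guide pseudouridylation, the median was 0.10 with the scrambled and -0.70 with the Airn siRNA in the authors' deposited table, and all 23 differences were negative (median -0.69). Over 13 other small RNAs (Y RNAs, vault RNA, several U RNAs, ribonuclease P-like RNAs, Rmrp, Rn7sk and Terc), the medians were -0.78 and -1.43 in the authors' deposited table, and 11 differences were negative. The 50 rows of C/D small nucleolar RNAs, which guide ribose methylation, had medians of -0.285 and -0.342 in the authors' deposited table and a median difference of 0.068. Their lower quartile went from -0.41 to -0.853, and the share of rows below 0 went from 66.0% to 82.0%, so this group was mixed. It was counted by rows, while the groups above were counted by gene. Rmrp, the RNA of ribonuclease MRP, went from -0.07 to -1.43 in the authors' deposited table, and Snora69 went from 0.36 to -2.14. No single member passed the test of the difference.

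ND6, the messenger read from the light strand, was lower with both siRNAs in the authors' deposited table (-2.59 and -2.60), while ND1 (0.54) and ND3 (0.55) were higher with the scrambled siRNA. The other single-gene rows in the authors' deposited table ranged from -0.43 for ND4L to 0.31 for ND2 with the scrambled siRNA and were not called. Of the mitochondrial rows shared by several symbols, that of ATP6, ATP8 and Gm10925 was called lower with the scrambled siRNA (-0.60, adjusted p = 0.0128). It stood at -0.62 with the Airn siRNA (adjusted p = 0.0516), and the other shared rows were not called. Among 20 replication-dependent histones, whose messengers lack a poly(A) tail, 5 were lower and 2 higher with the scrambled siRNA in the authors' deposited table (3 and 1 adjusted over the list alone), with Hist1h2ae at -1.09 and the linker histone Hist1h1c at 0.62. Among the list of small nucleolar RNA hosts and nuclear non-coding RNAs, Gas5 (1.32) and Snhg1 (1.35) were higher and Dleu2 (-1.31) and Meg3 (-0.92) lower with the scrambled siRNA in the authors' deposited table.

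Of the collagen and extracellular matrix list, 11 of 52 members were higher and 6 lower with the scrambled siRNA in the authors' deposited table (7 and 5 adjusted over the list alone), with Fbln5 at 0.99 and Lox at -0.88. Chaperones of the endoplasmic reticulum had 11 of 25 members higher and 1 lower in the authors' deposited table (17 and 1 adjusted over the list alone), with Sdf2l1 at 1.30. The p53 and apoptosis list had 12 of 33 higher and 2 lower in the authors' deposited table (15 and 2 adjusted over the list alone), with Trp53inp1 at 1.26, and the insulin and growth-factor list 27 of 42 higher and 4 lower (30 and 4 adjusted over the list alone), with Rheb at 1.51.

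The largest differences of the whole table, from -4.86 to 3.40 with the scrambled siRNA, belonged to rows without a symbol. Whether these rows are array controls was not examined, so they cannot be read as strongly bound or depleted transcripts. Of all 10302 rows without a symbol, 812 were called higher and 1866 lower in the authors' deposited table. The variance of the standardised differences between siRNAs was 0.885 times that of a t value over rows and 0.827 times over genes. Simulated arrays over 35554 rows gave 0.994 without replicate effects, and 0.651 with replicate effects of an arbitrary size left out of the fit. With standard errors rescaled to the observed spread over genes, 0 genes passed and Mx2 had an adjusted p of 0.0648.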
